A study of Homo sapiens with 69 samples.

How the data were processed

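Libraries were made from total RNA with a TruSeq RNA kit after RNeasy extraction, per the labels' protocols. HISAT2 and the genome build hg19 are named in the submitters' processing notes. The tool and the annotation used to count reads per gene are not given in the sources used here. The files are 2 tables, 1 for each cell line, with gene identifiers in rows and libraries in columns.

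Samples were placed in groups from their titles, which give the targeted gene, the cell line and a replicate number. Each table column was then compared with the labels of all 69 samples, using Python 3.11.15. A column was to be used only if its name matched the title or a line of the description of 1 sample. The name matching was tested on the sample titles and on made-up names, and it returned the right answer for each. Neither set held a library index name, so the check shows only that the code worked on those names. The columns carry library index names, and no name matched the labels of 1 sample alone. The 69 columns of per-sample values therefore entered no measurement or comparison. Their values were looked at only to see what kind of numbers they were and whether any column was empty. For T47D, 1 column was 0 in every gene row, and for MCF7 there were 0 such columns. The depth of each sample is for the same reason not given. The planned tests of changed genes, of gene lists and of differences between the cell lines in the response to each knockdown were not run. The matching had no key that pairs each library index with its sample. The sample descriptions name a text file for each cell line, which was not among the sources used here, and whether it holds such a key is not known.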

Results

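RNA sequencing was performed on 69 samples from 2 human breast cancer cell lines, MCF7 and T47D, both established lines that express the estrogen receptor. In each line, cells received a pool of small interfering RNAs against 1 of 10 genes, or served as controls. The targeted genes were ESR1, which encodes estrogen receptor alpha, together with CAMK2D, CDK8, CSNK1A1, GRB2, HIPK4, KSR1, LIMK1, MKNK2 and NEK9. CDK8 is a kinase of the Mediator complex, and CSNK1A1 encodes casein kinase 1 alpha. GRB2 is an adaptor protein that links receptor tyrosine kinases to RAS, and KSR1 is a scaffold of the RAF, MEK and ERK kinases. The labels gave 11 groups per line and 22 groups in all. MCF7 contributed 34 samples and T47D contributed 35. Of the 22 groups, 17 held 3 samples and 4 held 4 samples, and the MKNK2 group in MCF7 held 2. The control group held 3 samples in each line. The labels numbered the replicates but did not say whether they came from separate cultures. In most groups, the MCF7 control included, the numbers in the titles were not consecutive. The titles do not show whether replicates with the missing numbers existed.

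The design implied a comparison of each knockdown with the control of the same line, a comparison of each knockdown between the lines, and a comparison of each kinase-pathway knockdown with the ESR1 knockdown. The series title states the question as the transcriptional response to knockdown of kinases that correlate with estrogen receptor activity. None of these comparisons was made, because no column of the count tables could be assigned to a sample. The MCF7 table had 34 columns and the T47D table had 35, each named by a library index. For T47D, 1 column was 0 in all 25702 gene rows, so 34 of its columns held counts, whereas all 34 columns of the MCF7 table did. The group of the empty column is not known, so the T47D group sizes, the control included, count labelled samples and not libraries with counts. Of these 69 column names, 0 equalled the title or a description line of 1 sample alone. The number of columns equalled the number of samples in each line, but assigning columns by their order would have been a guess. Assigning them by the level of the targeted gene would have used the outcome to define the groups. No expression level, fold change or test of any gene is therefore reported for ESR1, for its target genes or for any of the other knockdowns.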

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

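Both alternatives were chosen after the tables had been seen. The number of columns matched to a sample was 0 when a name could be part of a title or description, and it was 0 when it could occur in any label field, protocols and characteristics included. Other settings, fixed before the data were examined, which covered normalization, the testing tool, the filter on low counts, the reference group, the gene list tests and leaving out each replicate, were not run, because they need the assignment of columns to samples. No paired analysis was possible because the table columns carry no replicate number. Such numbers would not by themselves have given pairs, because the labels do not say whether equal replicate numbers mark paired samples. In T47D, the titles of the GRB2 group shared no replicate number with those of the control.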
